A study of Mus musculus with 6 samples.

How the data were processed

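Brown adipose tissue, the heat-producing fat depot, was compared between wild type and Cd36 null male mice of 3 months after an overnight fast. Cd36 encodes a membrane protein that takes up long-chain fatty acids. Each genotype was measured on 3 arrays, 6 in all, with Illumina bead arrays that report 1 colour. The labels number the samples 1 to 3 in each genotype. Nothing in the labels says whether they came from separate animals, so the p-values measure the spread between these samples, which may be partly technical.

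The deposited scanner table holds an intensity on a linear scale for each probe and array, not normalised between arrays, per the file headers. Beside each intensity it holds a detection p-value, per the file headers. The authors' processed value table holds values on a log2 scale, and limma is named in the submitters' processing notes without a version. The exact steps behind the authors' table are not given in the sources used here. Set against the scanner values, it differed by at most 0.024 log2 from neqc with an offset of 50, which fixes its scale and direction, and its column medians lay between 5.92 and 5.93. Every per-sample column of both tables was used.

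Of the 45267 probes in the authors' table, 34875 had 1 gene symbol in the platform annotation used here, 18 had several and 10374 were not listed and stayed unnamed. Of the probes with 1 symbol, 34808 were found in the RefSeq gene table of GRCm38.p6, and 10 symbols were updated from it. The array files name no genome build, so no coordinate is printed, and that table served only for names and for which genes lie next to each other. A further 970 probes were in the scanner table only. They were kept for background correction and normalisation and left out of the tests of genes.

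Intensities were corrected and normalised with neqc in limma 3.58.1 under R 4.3.3. This fits a normal background whose mean and spread were inferred from the detection p-values, adds an offset of 16, takes log2 and applies quantile normalisation over the 6 arrays. Probes with a detection p under 0.05 on at least 3 arrays were tested, 17912 in all. They covered 10150 genes, and 2565 of these probes had no gene name here. Genotypes were compared per probe with lmFit and eBayes in limma, without trend or robust estimation, and adjusted by Benjamini-Hochberg with a threshold of 0.05. Every adjusted p of a gene comes from this moderated test unless another is named. All differences are Cd36 null minus wild type on the log2 scale, where the offset shrinks the differences of dim probes. Where no array of a genotype had detected a probe, the difference is given as a bound. The bound sets the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among detected probes and the probe's own.

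Gene lists were tested with camera, which asks whether a list's genes moved relative to all other genes, with a preset correlation of 0.01 between genes. Each gene was represented by its brightest tested probe. The 29 lists, the groups, the tests and the rule for naming genes were set before the data were examined. They comprise pathways of fat, energy and stress metabolism, immune and matrix genes, markers of other cell types, and genes that lie near Cd36. Adjustment was over these 29 lists. A further 3 lists (hepatocyte markers, lysosomal hydrolases and membrane proteins, glycogen metabolism) were added after seeing the data and adjusted over all lists together. With the correlation estimated from the data instead, 0 of the 32 lists passed. Rotation tests (fry) of whether a list moved 1 way on balance, and of change in either direction, were run beside camera.

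Named genes are Cd36; the 12 largest rises and the 12 largest falls among genes past the threshold whose null arrays all lay on 1 side of the wild type arrays, leaving out symbols of clones and gene predictions; up to 4 members of smallest p in each list; and 14 genes of brown fat, fasting and coenzyme Q metabolism fixed in advance. Of those 14, 1 is not reported here. Members beyond this rule are named in the text only as added after their values were seen.

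The fit and the camera test were tried on simulated normalised values, for the comparison of null with wild type. These had the means of the 17912 probes, spreads drawn at random from the fitted prior, and no correlation between probes. Background correction, normalisation and the filter were not tested. With 200 probes changed, 97% of changes of 2 log2 units and 44% of changes of 1 unit were recovered, with 8 false calls, and 0 calls were made with nothing changed. Shifts shared by many genes of 1 array, as seen below for liver and muscle transcripts, were not simulated. The false calls therefore do not give the rate on the real arrays. The real arrays gave 1296 changed probes, more than the 200 simulated, and the adjustment depends on how many probes change. The recovered shares may therefore differ on the real arrays, where a change under 1 log2 unit could still often be missed. Alternatives covered the background correction, the offset, the scaling, the authors' own values, the filter, the variance model, array weights, the replicate number as a block, each array left out, and other list tests. The files name no array chips, so a fit with the chip as a block was not run.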

Results

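RNA of brown adipose tissue from wild type and Cd36 null male mice, fasted overnight, was hybridised to whole-genome expression arrays, 3 per genotype. The comparison asks how the transcripts of this depot differ when the fatty acid transporter Cd36 is missing. Between 16929 and 17035 probes were detected on the wild type arrays and between 18139 and 19199 on the null arrays. Normalised values correlated across tested probes at 0.970 to 0.988 within a genotype and at 0.955 to 0.966 between genotypes. The number of arrays limits the precision of every value given here.

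The targeted gene could not serve as a check of the genotype labels. The array carried 1 probe named Cd36, and its signal lay at background. It averaged 4.96 ± 0.47 log2 (SD, n = 3) in wild type and 4.55 ± 0.05 (SD, n = 3) in null tissue, a difference of -0.40 ± 0.23 (SE) with an adjusted p of 0.369 in limma. It was detected on 1 of 3 wild type arrays and on 0 of 3 null arrays. Raw intensities were 118, 109 and 118 in wild type replicates 1 to 3 and 104, 104 and 106 in null replicates 1 to 3. Whether this probe lies inside the deleted part of the gene is not given in the sources used here. Another probe for Cd36 may be among the 10374 probes without an annotation here, and a signal at background is no measure of the transcript.

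Macrophage, extracellular matrix and amino acid stress genes were higher in Cd36 null brown fat, together with a few PPAR target genes, while the list of thermogenic genes did not pass. With camera, these groups passed as lists only at its preset correlation. With an estimated correlation the camera adjusted p was 0.131 for macrophage, matrix and stress genes and 0.209 for PPAR targets. In fry, which asks whether a list moved 1 way on balance, macrophage, matrix and stress lists passed (adjusted p = 0.00271 each). The list of PPAR targets passed fry too (adjusted p = 0.00373). Liver-type transcripts were higher as well (list median 2.46), unevenly over the null arrays, and muscle transcripts were lowest on null replicate 3. Gpnmb, a glycoprotein of lipid-laden macrophages, rose by 4.22 ± 0.24 log2 (SE, n = 3 per genotype, adjusted p = 6.33e-05), with a second probe up by 2.89. Mthfd2, a mitochondrial enzyme of folate metabolism, rose by 3.49 ± 0.18 (adjusted p = 4.68e-05), with a second probe up by 3.01. Prkag2, a regulatory subunit of the energy sensor AMPK, fell by 4.18 on the log2 scale (SE 0.19, adjusted p = 4.05e-05), by its only tested probe. It was detected on 1 of 3 null arrays, so the null level lies near background and the size of the fall is uncertain. Prkag2 lies on the chromosome of Cd36, and a base mismatch under this probe stays open, as described below. In all, 897 probes were higher and 399 lower in null tissue at an adjusted p under 0.05 in limma. These belonged to 635 genes with a higher probe and 282 with a lower probe, and 1 gene had probes in both directions. Changes of at least 2-fold made up 552 of the higher and 127 of the lower probes. Among all tested probes, 27.5% had genotypes that did not overlap, against 10% by chance with 3 arrays per group. Rises made up 69.2% of the changed probes, and 85.6% (1359 higher, 228 lower) when arrays were scaled by their medians instead of quantiles. The share was 59.8% (644 higher, 433 lower) when probes had to be detected on all 6 arrays, and 59.9% with array weights. The median difference over all tested probes was -0.05 log2 with quantile normalisation and 0.08 with median scaling. The count of changed probes fell from 1296 to 704, 589 and 724 when wild type replicate 1, wild type replicate 2 or null replicate 2 was left out.

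**Figure D1:**
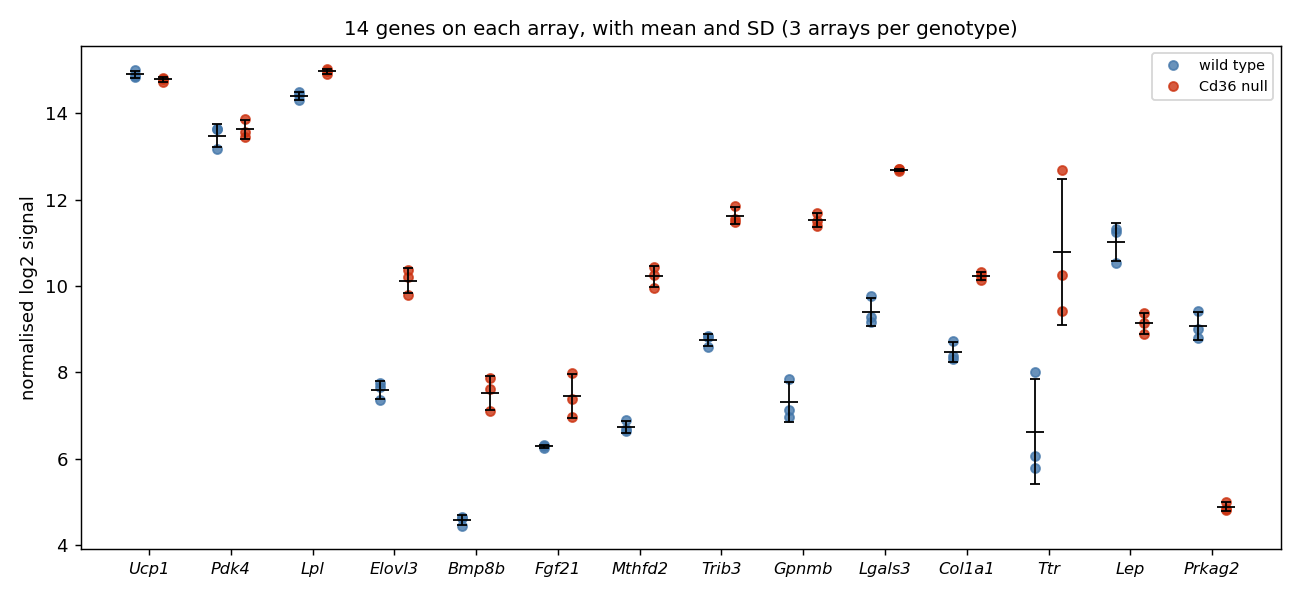
Normalised log2 signal (vertical axis) of 14 genes on each of the 6 arrays, wild type in blue and Cd36 null in red, with the mean and SD of 3 arrays per genotype as bars. Ucp1 and Pdk4 lie at similar levels in both genotypes, the 3 null arrays of Gpnmb, Mthfd2 and Elovl3 lie above all wild type arrays, and those of Lep and Prkag2 lie below them.

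Macrophage markers rose together. Of 21 measured members, 18 rose, 0 fell and 3 did not pass, and 20 rose adjusted over the list alone. The median change was 1.52 log2 (camera adjusted p = 5.98e-23; adjusted p = 0.131 with an estimated correlation). Besides Gpnmb, Lgals3, a galactoside-binding lectin, rose by 3.28 ± 0.19 log2 (SE, adjusted p = 7.19e-05) and Lyz2, the macrophage lysozyme, by 2.05 ± 0.17 (adjusted p = 3.27e-04). Trem2, a lipid-sensing receptor, was detected on 3 of 3 null and 0 of 3 wild type arrays and was at least 4.61-fold higher (adjusted p = 3.06e-04). The list's level on the null arrays was alike, at 1.48, 1.62 and 1.58 log2 above the wild type mean in replicates 1 to 3. On wild type replicates 1 to 3 it stood at -0.184, -0.113 and 0.316. Lymphocyte and lymph node markers rose in 10 of 13 members, and in 11 adjusted over the list alone, with 0 falls (median 1.08, camera adjusted p = 4.78e-09; adjusted p = 0.131 with an estimated correlation). Their members of smallest p were Coro1a, H2-Aa, H2-Ab1 and Cd2. Coro1a, an actin-binding protein of leukocytes, rose by 1.59 log2, with its 4 probes between 0.672 and 1.59. The class II antigen-presentation genes H2-Aa and H2-Ab1 rose by 1.27 and 1.26. The T cell adhesion gene Cd2 was at least 1.26-fold higher, a call that ended with the authors' values. The lymphocyte list's median was 0.59 with the authors' values and 0.41 without background correction.

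Genes of inflammation and of the interferon response were also higher. Of 18 measured inflammatory and acute-phase genes, 9 rose, 0 fell and 9 did not pass, and 14 rose adjusted over the list alone (median 1.25, camera adjusted p = 1.14e-10; adjusted p = 0.131 with an estimated correlation). The chemokines Ccl5 and Ccl4 rose by 2.56 ± 0.29 and 2.01 ± 0.16 log2 (SE), from wild type levels near background, as they were detected on 2 and 1 of 3 wild type arrays, so these sizes are uncertain. The list's median was 0.75 with the authors' values and 0.52 without background correction. Il1rn, the interleukin-1 receptor antagonist, was at least 2.09-fold higher, with a second probe up by 0.936 log2, and the receptor Tlr2 rose by 1.34 log2. Of 18 interferon response genes, 8 rose, 0 fell and 10 did not pass, and 12 rose adjusted over the list alone (median 0.69, camera adjusted p = 3.95e-09; adjusted p = 0.214 with an estimated correlation). Usp18 rose by 1.81 ± 0.19, Rsad2 by 1.37 ± 0.20, Oasl2 by 1.20 ± 0.15 and Oas2 by 1.18 ± 0.15 log2 (SE), with a second probe of Oasl2 at 0.56 without passing.

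Extracellular matrix genes rose in 15 of 27 measured members, with 0 falls and 12 not passing. Adjusted over the list alone, 18 rose. The median change was 0.83 log2 (camera adjusted p = 1.62e-12; adjusted p = 0.131 with an estimated correlation). The collagen genes Col1a1 and Col1a2 rose by 1.76 ± 0.17 and 1.47 ± 0.20 log2 (SE). Lum, a collagen-binding proteoglycan, rose by 1.31 ± 0.16, and Thbs2, a matrix glycoprotein, by 1.11 ± 0.15. Cell cycle genes were higher as a list, with 2 of 14 members rising, 0 falling and 12 not passing, and with 6 rises and 1 fall adjusted over the list alone (median 0.38, camera adjusted p = 0.0129; adjusted p = 0.422 with an estimated correlation). The members that rose were Top2a, a topoisomerase of dividing cells, at least 1.29-fold higher, and Mcm7, a replication helicase subunit, by 0.73 log2. That list did not pass without wild type replicate 3 (adjusted p = 0.0738) or without null replicate 3 (adjusted p = 0.0664), and the call of Mcm7 ended when any array but wild type replicate 3 was left out, and that of Top2a when any but null replicate 2 was.

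The integrated stress and amino acid response was higher in null tissue. Of 23 measured members, 10 rose, 0 fell and 13 did not pass, and 11 rose adjusted over the list alone (median 0.53, camera adjusted p = 1.65e-07; adjusted p = 0.131 with an estimated correlation). Besides Mthfd2, Trib3, a pseudokinase induced by this pathway, rose by 2.88 ± 0.17 log2 (SE, adjusted p = 7.66e-05), with its 3 probes between 2.15 and 2.88. Psat1, an enzyme of serine synthesis, rose by 1.81 ± 0.23 and Ddit4, an inhibitor of mTORC1, by 1.22 ± 0.21. Endoplasmic reticulum chaperones and their partners did not pass as a list (median 0.18, camera adjusted p = 0.0619). Of 17 members, 1 rose, Sel1l by 0.93 log2 on 1 of its 3 probes with another at 0.22, and adjusted over the list alone 5 rose and 1 fell. The list was higher in 10 of 22 alternatives, among them the authors' values (adjusted p = 0.0471), no filter (adjusted p = 0.0411), and wild type replicate 1 or null replicate 1 left out (adjusted p = 0.0238 and 0.0457). Its median ranged from 0.111 to 0.416 over the alternatives. Sel1l did not pass without wild type replicate 1, 2 or 3 or null replicate 2. Sdf2l1, Herpud1 and Edem1 differed by 0.76, 0.51 and 0.74 without passing over all genes. Oxidative stress defence did not pass either (median 0.09, camera adjusted p = 0.272), with 1 of 23 members higher and 1 lower. Gsta3, a glutathione transferase, rose by 1.46 log2, with a second probe at 0.39 without passing, and Sod3, the extracellular superoxide dismutase, fell by 0.78. The call of Sod3 ended when any array but null replicate 2 was left out. Srxn1 and Nqo1 differed by 0.70 and 0.52 without passing over all genes by their brightest probes. However, 1 of the 3 probes of Srxn1 passed as higher, with its probes between 0.431 and 0.834. Adjusted over the list alone, 2 rose and 1 fell.

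Several PPAR target genes of fasting and peroxisomal lipid metabolism rose. Of 17 fasting-responsive PPAR targets, 4 rose, 0 fell and 13 did not pass, and 4 rose adjusted over the list alone (median 0.35, camera adjusted p = 3.98e-05; adjusted p = 0.209 with an estimated correlation). Acot2, a mitochondrial thioesterase, rose by 2.43 ± 0.17 log2 (SE), although a second tested probe of it differed by -0.30. Acaa1b and Ehhadh, enzymes of peroxisomal beta oxidation, rose by 1.96 ± 0.16 and 2.06 ± 0.25. Fgf21, a fasting hormone, rose from 6.29 ± 0.03 to 7.45 ± 0.51 (SD, n = 3, adjusted p = 0.0225 in limma), and did not pass without wild type replicate 1, 2 or 3 or null replicate 2 (highest adjusted p = 0.0787). The peroxisomal list, with 3 rises, 0 falls and 18 members not passing, and 4 rises adjusted over the list alone, was higher by a median of 0.18 log2 (camera adjusted p = 0.0271; adjusted p = 0.459 with an estimated correlation). It also held Acox2, a branched-chain acyl-CoA oxidase, which rose by 1.17 log2, and Acot8, which differed by 0.55 without passing. The list did not pass without wild type replicate 3 (adjusted p = 0.103) or null replicate 3 (adjusted p = 0.059), nor with median scaling (adjusted p = 0.0768).

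The thermogenic program did not move 1 way as a list. Of 28 measured members, 3 rose, 3 fell and 22 did not pass, and 3 rose and 7 fell adjusted over the list alone (median -0.14, camera adjusted p = 0.272). With median scaling the list was lower (adjusted p = 0.0447). Over the alternatives its median ranged from -0.178 to 0.00291. Ucp1, the uncoupling protein that makes heat, was among the brightest probes of the array and averaged 14.90 ± 0.08 in wild type and 14.78 ± 0.05 in null tissue (SD, n = 3; adjusted p = 0.704 in limma). Near the top of the scale, differences can be compressed. Bmp8b, a secreted factor of brown fat, was detected on 3 of 3 null and 0 of 3 wild type arrays and was at least 5.29-fold higher (adjusted p = 2.04e-04). Elovl3, a fatty acid elongase induced by cold, rose from 7.59 ± 0.21 to 10.12 ± 0.29 (SD, n = 3, adjusted p = 3.06e-04 in limma). Epsti1 was at least 1.41-fold higher, and Cpn2, a carboxypeptidase subunit, fell by 1.29 log2. Ppargc1a, a coactivator of mitochondrial genes, differed by -0.69 ± 0.22 (adjusted p = 0.099) and Dio2, the thyroid hormone deiodinase, by 0.19 ± 0.23 (adjusted p = 0.702).

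Genes of fatty acid uptake lay near the threshold as a list. Of 23 measured members, 3 rose, 0 fell and 20 did not pass, and 6 rose adjusted over the list alone (median 0.12, camera adjusted p = 0.0679). Slc27a2, a fatty acid transport protein and acyl-CoA synthetase, rose by 1.06 log2, Fabp3, a fatty acid binding protein, by 0.80 and Scarb2, a lysosomal membrane protein of the Cd36 family, by 0.63, with a second probe at 0.22 without passing. The list was higher in 11 of 22 alternatives, among them the authors' values (adjusted p = 0.0395), no filter (adjusted p = 0.0143), and wild type replicate 1 or null replicate 1 left out (adjusted p = 0.0439 and 0.0295). Its median ranged from 0.0643 to 0.291 over the alternatives. Slc27a2 did not pass without wild type replicate 2. The calls of Fabp3 and Scarb2 each ended without wild type replicate 1, 2 or 3, without null replicate 2 or without null replicate 3, and that of Scarb2 also without null replicate 1. Lpl, the lipase that frees fatty acids from circulating lipoproteins, differed by 0.57 ± 0.15 (SE, adjusted p = 0.055) and Slc27a1 by 0.42 ± 0.16 (adjusted p = 0.163). The only probe of Fabp4 was dim and differed by -0.19 ± 0.27 (adjusted p = 0.745). None of 22 genes of mitochondrial fatty acid oxidation passed (camera adjusted p = 0.497, median 0.09), over all genes or adjusted over the list alone. Of these, 4 had the smallest p, namely Acad12, Cpt1b, Slc22a5 and Acaa2, at -0.62, 0.35, 0.38 and -0.38 log2. Pdk4, the kinase that restrains pyruvate oxidation, differed by 0.15 ± 0.19 (adjusted p = 0.715).

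Few genes of lipid storage and synthesis passed, in mixed directions, and none of their lists passed in the main fit. Of 32 genes of lipolysis, lipid droplets and triglyceride synthesis, 1 rose, 2 fell and 29 did not pass, and 2 rose and 3 fell adjusted over the list alone (median 0.02, camera adjusted p = 0.918). Pnpla3, a lipid droplet protein, fell by 1.59 log2 and Gpd1, a source of glycerol phosphate, fell by 0.73, while Gpat3, an acyltransferase, rose by 1.06 on 1 of its 2 probes. Cidec differed by 0.61 without passing. Of 20 genes of de novo lipogenesis, 2 fell, 1 rose and 17 did not pass, and 4 fell and 1 rose adjusted over the list alone (median -0.23, camera adjusted p = 0.0826). Mlxipl, which encodes the transcription factor ChREBP, fell by 1.23 log2 on 1 of its 2 probes and Srebf1, another lipogenic factor, fell by 0.66, while the desaturase Fads1 rose by 1.04. Fasn differed by -0.73 without passing. This list was lower in 8 of 22 alternatives, among them the authors' values (adjusted p = 0.0486), no filter (adjusted p = 0.0411), median scaling (adjusted p = 0.00446) and null replicate 3 left out (adjusted p = 0.00924). Its median ranged from -0.368 to -0.118 over the alternatives. The call of Srebf1 ended without any of the 6 arrays, that of Gpd1 without any but null replicate 3, and that of Gpat3 without wild type replicate 2. None of 18 genes of mevalonate and cholesterol synthesis passed, over all genes or adjusted over the list alone (median -0.21, camera adjusted p = 0.0962), with Nsdhl at -0.73, Cyp51 at -0.63, Sc5d at -0.67 and Pmvk at -0.44. Without null replicate 3 that list was lower (adjusted p = 0.00996).

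Respiratory chain and ATP synthase genes were slightly lower as a list, by a median of -0.11 log2 over 67 members (camera adjusted p = 0.0151; adjusted p = 0.416 with an estimated correlation). Only Cox7b fell, by 0.72, 66 members did not pass, and none passed adjusted over the list alone. Cox7b did not pass when any of the 6 arrays was left out, and the list did not pass without wild type replicate 3 (adjusted p = 0.0738). Cox7a2, Atp5j and Ndufb11 differed by -0.63, -0.48 and -0.41 without passing. Of 11 genes of coenzyme Q synthesis, 1 fell, 2 fell adjusted over the list alone and the list did not pass (median -0.06, camera adjusted p = 0.604). Coq10a, a coenzyme Q binding protein, fell by 0.65 log2, a call that ended when any of the 6 arrays was left out. Coq2, Coq7 and Coq9 differed by -0.06 ± 0.20, -0.04 ± 0.17 and 0.09 ± 0.18 (SE). Coq7 and the median of the coenzyme Q list changed sign with median scaling. Coq4, Coq8a and Coq8b were at -0.58, 0.34 and 0.25 without passing. None of 19 genes of the tricarboxylic acid cycle passed, over all genes or adjusted over the list alone (median -0.04, camera adjusted p = 0.556), with Dlat, Pdhb, Sdhd and Fh1 at -0.47, -0.38, -0.34 and -0.33. With median scaling that list was lower (adjusted p = 0.0334). Of 22 genes of glucose uptake and glycolysis, 1 fell, Pygl by 0.77 log2, and none passed adjusted over the list alone (median -0.09, camera adjusted p = 0.566). Pygl, a glycogen phosphorylase, passed without null replicate 3 but not without any of the other 5 arrays. The glucose transporter Slc2a4 differed by -0.69, Hk1 by 0.71 and Slc2a3 by 0.37.

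**Figure D2:**
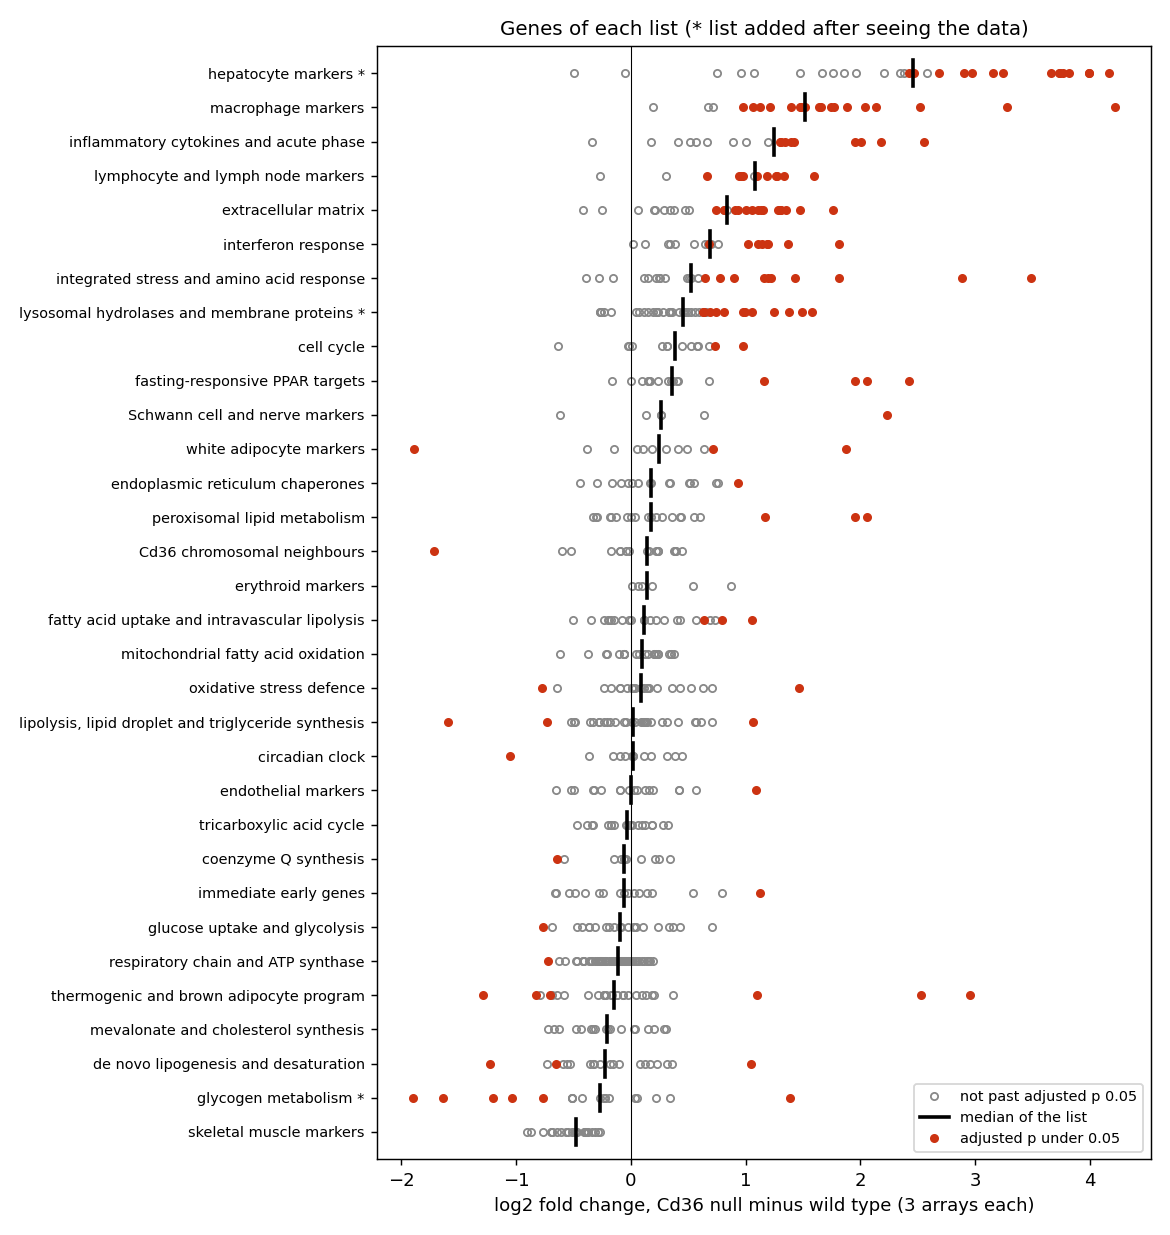
Log2 fold change of each measured gene (horizontal axis, Cd36 null minus wild type, 3 arrays per genotype) for each gene list (vertical axis), with filled points for genes at an adjusted p under 0.05, open points for the others and a bar at the list's median. Macrophage markers have a median of 1.52 and mitochondrial fatty acid oxidation genes a median of 0.09 with no filled point.

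Most of the largest rises of named genes outside these groups were of transcripts typical of liver, and these varied between null arrays. Of the 12 named genes with the largest rises, Ttr, Serpina1b, Ambp, Mup3, Apoc4, Serpina1d, Apoa1 and Ahsg belong to a hepatocyte list added after seeing the data, and Itih4 and Mup2 also encode plasma or urinary proteins of liver. Ttr, a thyroid hormone carrier of plasma, averaged 6.62 ± 1.22 in wild type and 10.79 ± 1.69 in null tissue (SD, n = 3, adjusted p = 0.0167 in limma). Itih4 and Mup2 rose by 3.76 ± 0.51 and 3.64 ± 0.60 log2 (SE). Itih4 was detected on 2 of 3 wild type arrays and its 3 probes ranged from 2.25 to 3.76, so its size is uncertain. Probes of the Mup and Serpina1 families can bind transcripts of near-identical copies, so their values are uncertain for the single gene. Over the 29 measured hepatocyte genes, 15 rose, 0 fell and 14 did not pass, and 22 rose adjusted over the list alone (median 2.46, camera adjusted p = 1.51e-11; adjusted p = 0.388 with an estimated correlation). The median was 1.62 without null replicate 1 and 1.26 without background correction. The list was chosen on these arrays, so its count is not independent evidence of direction. Its level stood 4.45, 1.27 and 1.78 log2 above the wild type mean on null replicates 1, 2 and 3, against -0.25, -0.19 and 0.40 on wild type replicates 1, 2 and 3. Ttr, Serpina1b, Ambp, Mup3, Apoc4, Serpina1d, Apoa1 and Ahsg did not pass without wild type replicate 1 or wild type replicate 2, nor Apoa1 without wild type replicate 3 (highest adjusted p = 0.114). Cyp2b10, a cytochrome P450 detected on 2 of 3 wild type arrays, rose by 4.05 ± 0.36 log2 (SE, adjusted p = 5.13e-04). Unlike the hepatocyte list, it was not highest on null replicate 1 (9.406, against 10.071 and 9.451 on null replicates 2 and 3). On the wild type arrays it was highest on replicate 3, as that list was. The call of Cyp2b10 was kept with each array left out and with the hepatocyte level as a covariate. With the array's hepatocyte level as a covariate, chosen after seeing the data, 142 probes passed, of which 139 were shared with the 1296, and leaving hepatocyte and Mup genes out of the count left 876 higher and 399 lower.

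Skeletal muscle transcripts set the null arrays apart from each other. The list stood at 0.58, -0.06 and -2.07 log2 from the wild type mean on null replicates 1, 2 and 3, and between -0.05 and 0.05 on the wild type arrays. On null replicate 3, all 24 measured muscle genes lay below every other array, by a median of -2.26 log2 against the mean of the other 5. None passed between genotypes, over all genes or adjusted over the list alone (median -0.48, camera adjusted p = 0.0606). Mb, Ampd1, Myh1 and Pgam2 differed by -0.87, -0.90, -0.70 and -0.77. The list was lower in 11 of 22 alternatives, among them the authors' values (adjusted p = 0.0471). Without null replicate 3 it turned higher, with a median of 0.28 (adjusted p = 0.00996), and without null replicate 1 or 2 it was lower (adjusted p = 9.71e-07 and 0.00418), while the macrophage list stayed higher without that array (adjusted p = 5.24e-23).

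**Figure D3:**
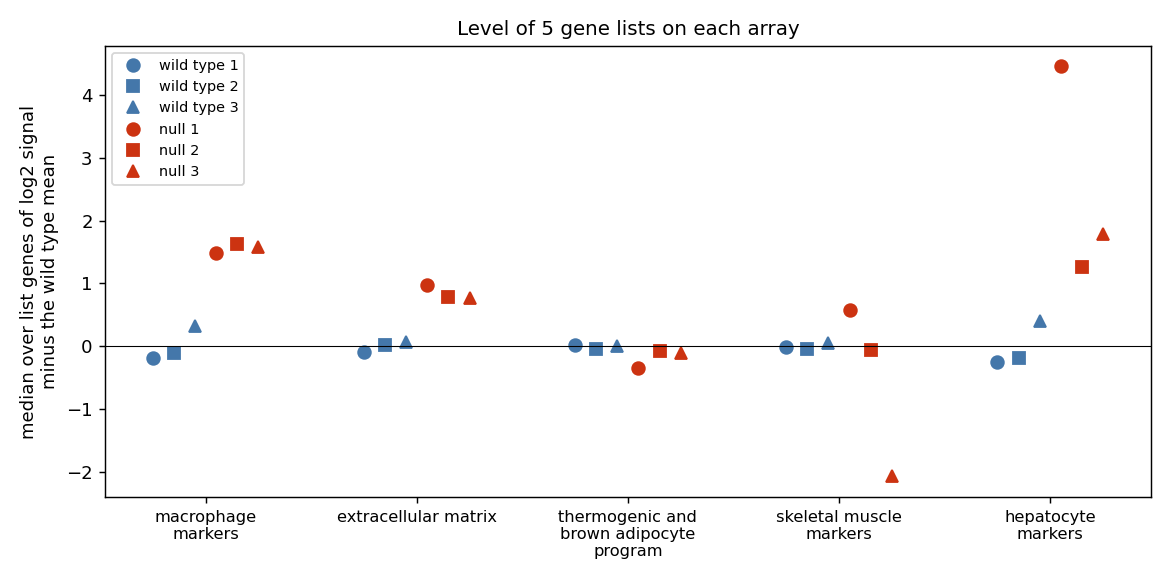
Level of 5 gene lists on each array, as the median over the list's genes of the log2 signal minus the wild type mean (vertical axis), with blue for wild type, red for Cd36 null and a symbol for each replicate. Macrophage markers lie between 1.48 and 1.62 on the null arrays, hepatocyte markers between 1.27 and 4.45, and skeletal muscle markers at -2.07 on null replicate 3.

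Markers of white adipocytes, endothelium, nerve and red blood cells did not pass as lists with camera. Of 12 white adipocyte markers, 2 rose and 1 fell, both over all genes and adjusted over the list alone (median 0.25, camera adjusted p = 0.152). Lep, which encodes leptin, fell from 11.03 ± 0.44 to 9.14 ± 0.24 (SD, n = 3, adjusted p = 0.0024 in limma). Agt, which encodes angiotensinogen, rose (adjusted p = 0.0055) by a size that is uncertain because its wild type level lay near background. Like the hepatocyte list, Agt was highest on null replicate 1 (7.318, against 6.615 and 6.556 on null replicates 2 and 3). Its call ended with the hepatocyte level as a covariate. As 64 of the 85 calls of named genes ended there, this does not set Agt apart. Mest was at least 1.25-fold higher on 1 of its 2 probes. Fgf10 differed by 0.49 without passing, although its other probe passed at 0.855. Without null replicate 3 the list was higher (adjusted p = 0.0487). Mest passed without null replicate 3 but not without any of the other 5 arrays. Among 18 endothelial markers, 1 rose, Cldn5 by 1.09 log2, and 1 rose and 1 fell adjusted over the list alone (median 0.00308, camera adjusted p = 0.999). Cldn5 did not pass without wild type replicate 2 or 3 or null replicate 1 or 3. Aqp1, Emcn and Vwf were at -0.66, -0.52 and 0.57 without passing over all genes by their brightest probes. However, 2 of the 3 probes of Aqp1 passed as lower, with its probes between -0.725 and -0.623. Among 6 Schwann cell and nerve markers, Mal, a myelin membrane protein also made by other cells, was at least 3.97-fold higher. A second probe of Mal rose by 1.08 log2. Adjusted over the list alone, 2 markers rose and 1 fell (median 0.26, camera adjusted p = 0.0962). That list was higher with fry (adjusted p = 0.00839). Mbp was at -0.62, with another probe at 0.107, and Sox10 was at 0.26. Ncam1, detected on 0 of 3 wild type arrays, was at least 1.26-fold higher, and none of these 3 genes passed over all genes. None of 6 erythroid markers passed, over all genes or adjusted over the list alone (median 0.14, camera adjusted p = 0.272), with Slc4a1 at 0.87, Alas2 at 0.54, Hbb-b2 at 0.18 and Hbb-bs at 0.09, the last with the opposite sign under median scaling. The probe of Hbb-bs read the top of the normalised scale on 3 arrays and that of Hbb-b2 was detected on 1 of 3 wild type arrays, so these differences cannot be sized.

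Clock and immediate early genes did not pass as lists. Of 13 clock genes 1 fell, Bhlhe40, a transcriptional repressor, by 1.05 log2, and 1 adjusted over the list alone (median 0.02, camera adjusted p = 0.918), with Dbp, Clock and Per3 at 0.38, -0.37 and 0.31. Of 17 immediate early genes 1 rose, Gadd45b by 1.12 log2, detected on 1 of 3 wild type arrays, which did not pass without wild type replicate 2, and 3 rose and 2 fell adjusted over the list alone (median -0.06, camera adjusted p = 0.751). The median of the immediate early list turned to 0.0515 with median scaling. Jun, Ier3 and Fos were at -0.54, -0.65 and 0.79 without passing over all genes.

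Among the 12 largest falls, Prkag2, Atg9b and Napepld lie on the chromosome of Cd36. Atg9b, an autophagy protein, fell by 2.21 log2 and Napepld, an enzyme of N-acylethanolamine synthesis, fell by 1.71. Of 17 measured genes listed as neighbours of Cd36, only Napepld fell, 16 did not pass and 1 fell adjusted over the list alone. The list did not move 1 way (median 0.14, with a mean of -0.04 and camera direction down, adjusted p = 0.999). In either direction it passed with fry (adjusted p = 3.38e-05), but so did 27 of the 29 lists fixed beforehand, this one included. Gnat3, Psmc2 and Phtf2 were at -0.60, 0.39 and -0.52. The other large falls were Cish, an inhibitor of cytokine signalling, by -2.42 ± 0.25 log2 (SE), Dlk1, a preadipocyte surface protein, by -1.99 ± 0.25, Ntrk3, a neurotrophin receptor, by -1.77 ± 0.31 (2 of 3 probes), Il17re, an interleukin-17 receptor subunit, by -1.74 ± 0.18, and Myo5c, a myosin motor, by -1.66 ± 0.21. Lep and Pnpla3 are given with their lists. Ppp1r3b, a glycogen-targeting subunit of protein phosphatase 1, fell by 1.63 log2, and Gbe1, the glycogen branching enzyme, was detected on 3 of 3 wild type and 0 of 3 null arrays and was at least 2.70-fold lower (adjusted p = 3.91e-04).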

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

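The tests of liver-type, macrophage and chromosome 5 genes were chosen after the results were seen; those of the other splits and of the listed neighbours were set before the data were examined.

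Of the 10 splits of the 6 arrays into 3 and 3, the real one gave 1296 changed probes and the highest of the others gave 0; 1 split, the real one, gave as many. With 10 splits the share cannot fall under 0.05.

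Transcripts typical of hepatocytes were higher on the null arrays, in 23 of 29 measured genes on every null array against every wild type array. The null arrays were not alike: null replicate 1 exceeded null replicate 2 by a median of 3.19 ± 0.12 log2 (bootstrap SE), more than null replicate 2 exceeded the wild type mean (1.27 ± 0.37). These SE are over genes and not over samples, with 1 array set against another, and the gap had been seen before the test was chosen. It therefore cannot decide how far genotype is a cause. Liver RNA carried over in different amounts cannot be told apart from regulation. An order over null replicates 1, 3 and 2 and the wild type mean was kept by 86.2% of the genes, but it was read from these same arrays, and genes regulated together would keep 1 order as well. Of the 47 list genes with a probe, 40, 29 and 32 were detected on null replicates 1, 2 and 3, and 12, 11 and 19 on wild type replicates 1, 2 and 3. Among those not detected, the single probes of Alb, Apob and Fgb, abundant liver transcripts, were detected on 0 arrays, and no liver sample shows whether these probes respond. A rise of these genes within the fat that varies between samples stays open as well.

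Macrophage markers rose by a median of 1.52 ± 0.15 log2 (bootstrap SE). Carry-over with liver tissue as the main source is argued against on the null arrays, since macrophage markers were not higher on null replicate 1 than on null replicate 2 (median -0.112 ± 0.056), while hepatocyte markers differed there by 3.19. On the wild type arrays both lists were highest on replicate 3 (0.316 and 0.398 log2 from the wild type mean), so a part carried over is not excluded. Carry-over of lymph node cannot be told apart from other sources of leukocytes: 6 of the 11 B and T cell genes on the array (54.5%) were detected on all 3 null arrays, and the 6 tested differed by a median of 0.95 ± 0.15, of which 4 rose past the threshold. Of the 6, Cd2, Cd3d and Cd3g were detected on 0 of 3 wild type arrays. They were tested only through the null arrays, which favours a rise. The 4 that rose were Cd2, Cd3d, Cd3e and Cd8b1. Cd8b1 averaged 10.76 log2 in wild type, where Cd3e averaged 5.10, so whether its probe reads T cells is uncertain. The B cell gene Cd79b differed by 0.30 (adjusted p = 0.497 in limma). Members other than Cd2 are named here after their values were seen. More macrophages in the fat, or a change within them, may equally underlie the rise, and neither was tested. As 20 of the 21 markers were detected on all 3 wild type arrays, the tissue holds these transcripts in both genotypes.

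Several genes on chromosome 5, which holds Cd36, were lower in null tissue. Among the 17 genes listed beforehand as neighbours, the odds ratio of changed genes was 0.734 (Fisher's exact test, one-sided p = 0.751), and among the 100 nearest measured genes it was 1.16 (one-sided p = 0.384), so a strain segment carried along with the null allele is neither shown nor excluded. Counting falls alone, 8 of the 100 fell against 2.05% of other genes, but falls near Cd36 on these arrays prompted that count, so it is no test of a strain segment. A base mismatch under single probes stays open. Of 9 other tested probes of the changed genes, 5 (55.6%) moved the same way past the threshold, but 2 of these belong to Abhd1, which rose by 3.08, and for the genes that fell it was 3 of 7 (42.9%). The other probes of Nos3 and Napepld fell, those of Gatad1 (-0.46 and -0.66), Asic3 (0.02) and Tmub1 (0.08) did not pass, and Prkag2, Atg9b and Supt7l had 1 tested probe each.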

How the results depend on the processing

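The covariate, the joint removal of null replicates 1 and 3 and the 3 added lists were chosen after seeing the data; where a result changed, the cause was not tested unless given. Counts of changed probes (1296, with 897 higher and 399 lower) moved by more than 1.5 times with array weights (2388, with 1430 and 958), with an unmoderated equal-variance comparison (296, with 203 and 93), without null replicates 1 and 3 together (405, with 338 and 67; the null side is then 1 array, all spread comes from wild type, and lists lost there show little) and with the hepatocyte level as a covariate (142, with 122 and 20; it runs with genotype). Median scaling gave 1359 higher and 228 lower. With single arrays left out the count ranged from 589 to 1043, with 476 to 780 higher and 113 to 263 lower. With the replicate number as a replicate block the counts were 868, 650 and 218. Deviations of same-numbered arrays correlated at 0.084, -0.018 and 0.03, so the numbers were not taken as pairs, and not every sample correlated best with its own number. The chip as a block was not run, as the files name no chips. The remaining alternatives stayed within 1.5 times. The Cd36 difference was not past the threshold under any alternative run, from -0.61 to -0.15.

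Of 29 lists fixed beforehand, 10 passed. With an estimated correlation 0 passed, with adjusted p of 0.131 for macrophage, matrix, inflammatory, lymphocyte and stress lists (medians 1.52, 0.834, 1.25, 1.08, 0.528), 0.214 interferon (0.689), 0.209 PPAR targets (0.354), 0.422 cell cycle (0.381), 0.416 respiratory chain (-0.11), 0.459 peroxisomal (0.176), 0.388 hepatocyte (2.46) and 0.105 lysosomal and glycogen (0.455, -0.267). With fry 9 passed, 8 of these 10 and the Schwann cell list (0.00839), and not respiratory chain (0.058), cell cycle (0.0861) or hepatocyte (0.0986); 27 passed in either direction. The peroxisomal list was also lost with median scaling (median 0.349), array weights (0.219), without null replicates 1 and 3 (0.163), and with single arrays left out ranged from 0.112 to 0.257. The respiratory chain was lost without null replicates 1 and 3 (-0.0923) and with the covariate (-0.0694), and ranged from -0.133 to -0.0804 with single arrays left out. The cell cycle list was lost when probes had to be detected on all 6 arrays (0.293; fewer genes) and without null replicates 1 and 3 (0.274), and ranged from 0.338 to 0.489 with single arrays left out. The hepatocyte list was lost with its own level as a covariate (0.264), by construction. The skeletal muscle list turned to 0.28 without null replicate 3, ranged from -1.02 to 0.28 with single arrays left out, and was -1.71 with the covariate. Other medians moved by more than 1.5 times with the call kept: without background correction inflammatory (0.521), lymphocyte (0.408), hepatocyte (1.26), peroxisomal (0.0882) and cell cycle (0.178); with an offset of 50 inflammatory (0.758) and lymphocyte (0.608); with the authors' values inflammatory (0.747) and lymphocyte (0.589); with no filter inflammatory (0.666), lymphocyte (0.664) and hepatocyte (1.48); with detection on all 6 arrays inflammatory (0.616). The same held for median scaling with respiratory chain (-0.183) and glycogen (-0.162), for the covariate with peroxisomal (0.4), for null replicates 1 and 3 left out with hepatocyte (1.17), and for single arrays left out with hepatocyte (1.62) and glycogen (-0.444, -0.426 and -0.44). For lists that did not pass, 49 of 418 alternatives passed in the same direction, most for fatty acid uptake (11 of 22), skeletal muscle (11), endoplasmic reticulum chaperones (10) and lipogenesis (8). In 22 of the 418, over 10 lists, the median had the opposite sign. Of 85 named genes past the threshold, 60 passed with every single array left out, and 0 reversed. Of the 85 calls, 64 ended with the covariate, 33 without null replicates 1 and 3, 22 with no filter, 15 with the replicate block and 10 with trend and robust estimation. Dim probes, near the offset, limit what these arrays can show.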

Other observations

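The tests in this part were all chosen after the results were seen.

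Some genes of glycogen metabolism fell and some genes of lysosomes rose in Cd36 null brown fat, by lists drawn up after seeing the data, which are not independent evidence of direction. Of 19 measured glycogen genes, 5 fell, 1 rose and 13 did not pass, and 7 fell and 1 rose adjusted over the list alone (median -0.27, camera adjusted p = 0.00305; adjusted p = 0.105 with an estimated correlation). The median was -0.44 without wild type replicate 1, -0.43 without null replicate 1, -0.44 without null replicate 2 and -0.16 with median scaling. Besides Gbe1 and Ppp1r3b, the glycogen-targeting subunits Ppp1r3c and Ppp1r3d fell by 1.20 ± 0.16 and 1.04 ± 0.15 log2 (SE), although a second probe of Ppp1r3d differed by -0.49 without passing. The rise was of Stbd1, a glycogen-binding protein of lysosomal transport, by 1.39 log2. Of 39 measured lysosomal genes, 12 rose, 0 fell and 27 did not pass, and 17 rose adjusted over the list alone (median 0.46, camera adjusted p = 5.08e-09; adjusted p = 0.105 with an estimated correlation). Ctsh, a cathepsin, rose by 1.58 ± 0.20 log2, Laptm5, a lysosomal protein of leukocytes, by 1.49 ± 0.16, Cd63 by 1.38 ± 0.20 (2 of 3 probes) and Npc1, a cholesterol transporter, by 1.24 ± 0.17 (SE), with another probe of Npc1 at -0.70. The lysosomal list stood 0.37, 0.51 and 0.50 log2 above the wild type mean on null replicates 1 to 3, beside 1.48, 1.62 and 1.58 for macrophage markers, and whether macrophages bring these transcripts was not tested.

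Several of the strongest rises belonged to probes without a gene name here. The probe ILMN_2635272 rose by 5.69 ± 0.37 log2 (SE, adjusted p = 0.00011), and ILMN_2772264, detected on 0 of 3 wild type and 3 of 3 null arrays, was at least 18.9-fold higher. In all, 142 of the higher and 65 of the lower probes had no single gene name. Of the 970 probes found only in the scanner table, 81 were detected often enough to be tested, and 0 passed an adjusted p of 0.05 in limma, with 9 at an unadjusted p under 0.05.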
